A study of Homo sapiens with 12 samples.

How the data were processed

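RNA of UM-UC-3, an established human bladder cancer cell line, was measured on 12 single-colour Illumina bead arrays. The arrays fell into 4 groups of 3: a control microRNA precursor, a miR-101 precursor, a control siRNA and an siRNA against EZH2. Each was transfected at 50 nM and RNA was taken after 72 h, per the labels' design text. That text describes triplicate transfections and gives nothing on separate cultures or days, so p-values measure the spread between these arrays, which may be partly technical. The number of arrays limits the precision.

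The raw table deposited by the authors holds an average bead signal, in intensity units, for 46713 probes on each array, per the file headers. No signal was below 49 and the highest was 66899.3, so no background had been subtracted. The same table gives a detection p-value for each probe and array, per the file headers. The software was BeadStudio, per the submitters' processing notes. Its version and the bead summary are not given in the sources used here. A further table deposited by the authors holds intensity values on a linear scale, with a median of 89.1 on every array. Its sorted values matched those of a quantile normalization of the raw signals to within 3.33e-06 on every array. Probe by probe only ranks were compared, with a lowest rank correlation of 0.999998 with the raw signals. That table was used only as an alternative. Array positions, from the column headers, put the control precursor and miR-101 arrays on 1 chip and both siRNA groups on the other. Controls lay at positions A to C and treated arrays at D to F. Median signal per array was 80.4 to 100.1 and mean signal 304 to 497, and 15453 to 16377 probes (33.1% to 35.1%) had a detection p-value under 0.05. Between 84 and 118 probes per array had a signal over 200 and yet a detection p-value of 0.05 or more, and the reason is not given in the sources used here. Correlation between arrays of a group was 0.992 to 0.999, and no pair of arrays had identical signals.

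Probes were named through their RefSeq accession in a table of the GRCh38.p14 assembly, which was used for names only. This named 18886 probes by accession, 1721 by current symbol and 854 by an older symbol. A further 7094 kept the symbol of the file and 18152 had no symbol. Of 29 symbols turned into dates in the file, 23 were resolved by accession and 6 were left unnamed. In all 28555 probes carried 24961 distinct gene names.

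Signals were background-corrected, quantile-normalized and set on a log2 scale with neqc in limma 3.58.1 (R 4.3.3), with an offset of 16 and the background taken from the detection p-values. Probes detected at p under 0.05 on at least 3 of the 12 arrays were kept (17844). A gene with more than 1 probe was represented by the probe with the highest mean, which left 13528 genes; 1099 of them had more than 1 probe, and 3127 passing probes had no name. A linear model with 4 groups was fitted to all 12 arrays with lmFit and eBayes in limma, with 8 residual and 1.36 prior degrees of freedom. The contrasts were miR-101 against control precursor, EZH2 siRNA against control siRNA, the difference between those responses, and control siRNA against control precursor. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Adjusted p-values are from this model unless stated otherwise. Fold changes are on the log2 scale after the offset, which understates the change of dim genes. A probe undetected on all arrays of a group was given only a bound there: the mean of the bright group against the mean of, per array, the higher of the lowest detected signal and the probe's own. Interval bounds are at the 95% level.

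In all 31 gene lists were fixed before the data were examined, along with the groups, the tests and the alternatives. Lists were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, all in limma, with adjustment over the lists of a comparison. Named genes followed a rule. It took EZH2, then the 10 largest rises and 10 largest falls in each treatment among genes past the threshold, detected on all 3 arrays of at least 1 group and without overlap between the groups. Symbols that were blank or began with LOC, HS., FLJ, KIAA or MGC, and numbered open reading frames, were left out. It added up to 4 members past the threshold with the smallest adjusted p for each list with a camera call or at least 3 members past the threshold. It also took the 5 largest differences each way for the contrast of the responses and for the controls, and 8 genes each way for those changed alike by both treatments. The results of 1 list and of 2 genes that the rule took are not reported here. Genes named outside it are said to have been chosen after their values were seen. Of 22 pairs of a named gene and a comparison with more than 1 probe, 3 had a probe of opposite sign.

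The procedure was tested on simulated data with 13528 genes. With miR-101 against its control, 68% of genes planted at a log2 change of 0.5 and 98% of those planted at 1 were called, and 4.60% of calls were false. With EZH2 siRNA the shares were 71%, 99% and 7.10%. Each size had 100 planted genes, in independent noise without chip, position or control effects. The shares are therefore not the error rates of the real calls.

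Alternatives were no background correction, an offset of 50, median scaling in place of quantile normalization, the authors' normalized table, no detection filter, a stricter filter (p under 0.01 on all arrays), every probe on its own, only the arrays compared, the replicate number as a block, array weights, a size threshold of 1.5-fold and leaving out each array in turn. Added later were the other control group, both controls exchanged, each chip normalized on its own and an intensity trend in eBayes. The planned test of miR-101 seed sites was not run, since no transcript sequences were used here. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and plots.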

Results

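Messenger RNA was profiled in UM-UC-3 cells, an established human bladder cancer line, after transfection with a control microRNA precursor, a miR-101 precursor, a control siRNA or an siRNA against EZH2. There were 3 arrays per group and 12 in all. The series title names the question, whether the microRNA miR-101 represses EZH2, the histone methyltransferase of Polycomb repressive complex 2 (PRC2). Between 15453 and 16377 of 46713 probes were detected per array. The dimmest array, miR-101 replicate 2, had a mean signal of 304 and the brightest, EZH2 siRNA replicate 1, 497. In all 13528 genes were tested.

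EZH2 fell with both treatments. With miR-101 its normalized log2 intensity went from 8.68 ± 0.276 to 7.78 ± 0.0910 (SD, n = 3), a log2 change of -0.90, which left 53.8% of the control level (95% interval 44.2% to 65.4%). The adjusted p from limma was 0.000300. With EZH2 siRNA it went from 8.62 ± 0.126 to 7.40 ± 0.0928, a change of -1.22 that left 43.0% (35.4% to 52.3%; adjusted p 0.000432). The other EZH2 probe gave -0.92 and -1.22. The changes with the treatments differed by 0.32, and the adjusted p of that difference was 0.205. EZH2 did not differ detectably between the controls (log2 change -0.06, adjusted p 0.788).

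**Figure D1:**
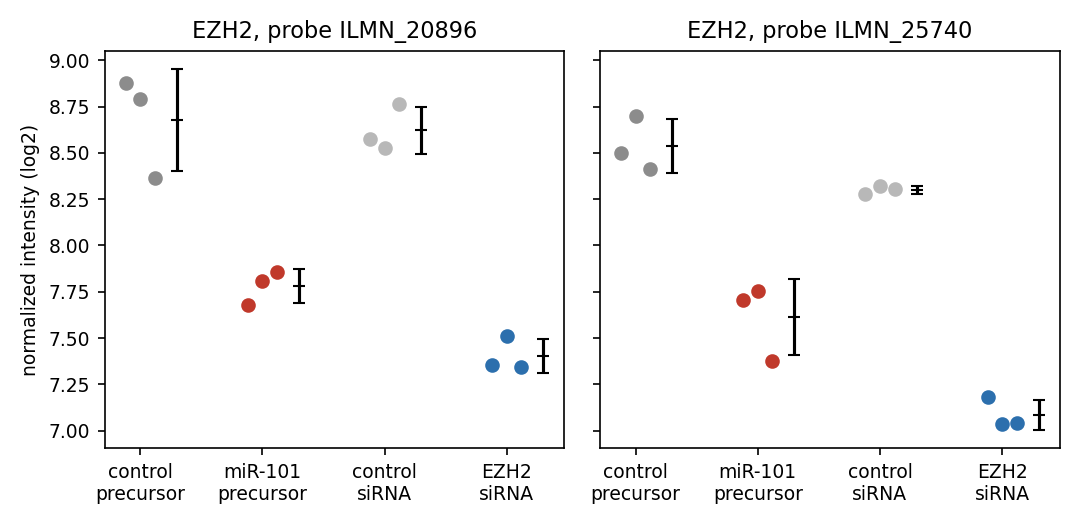
Normalized log2 intensity of the EZH2 probes on each of the 12 arrays, by transfection group, with points for arrays and bars for the group mean ± SD (n = 3). The probe used for the gene had means of 8.68 and 8.62 in the controls, 7.78 with miR-101 and 7.40 with EZH2 siRNA.

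The miR-101 precursor, set against the control precursor, was followed by lower messenger RNA of the DNA replication machinery and of mitosis. Of 39 S phase and replication genes, 37 fell and 0 rose (37 and 1 adjusted over the list alone), with a median log2 change of -1.25. Examples were the replicative helicase subunit MCM4 (-1.93), the origin-firing factor MCM10 (-1.98), the polymerase epsilon subunit POLE2 (-2.13) and GINS2 (-2.26), part of the helicase complex. UNG, the uracil-DNA glycosylase, was undetected by the probe used on all 3 miR-101 arrays, where its mean log2 intensity was 7.40. That lay above the lowest detected signal, so the bound is the plain estimate, 7.11-fold lower (adjusted p 2.86e-07). A second UNG probe gave -0.05. Of 36 G2/M genes 32 fell and 2 rose (33 and 2 adjusted over the list alone), with a median of -0.93. The spindle checkpoint gene MAD2L1 (-2.05), the mitotic kinesin KIF11 (-1.62), cyclin B1 (CCNB1, -1.56) and the anaphase activator CDC20 (-1.05) were among them. Camera gave adjusted p = 1.17e-18 for the S phase list and 9.74e-12 for the G2/M list. With an estimated correlation they were adjusted p = 0.00232 and 0.0345.

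Several other groups rose with miR-101. Of 27 autophagy and lysosome genes 19 rose and 2 fell, the same counts as adjusted over the list alone, including the ATG8-family gene GABARAPL1 (3.57), the lysosomal membrane gene LAMP2 (2.61), WIPI1 (1.70) and the sialidase NEU1 (1.36). A second LAMP2 probe gave 1.29. Of 28 genes of cholesterol and fatty acid synthesis 14 rose and 0 fell, with the same counts adjusted over the list alone; they included SC5D (2.29), IDI1 (2.12), HMGCS1 (1.31) and NSDHL (1.11), all enzymes of the sterol pathway. Of 28 interferon response genes 15 rose and 1 fell (16 and 1 adjusted over the list alone), among them IRF9 (2.55), a subunit of the interferon-activated factor ISGF3, and the induced genes IFI6 (2.34), IFI35 (1.90) and ISG20 (1.71). Of 20 genes of the unfolded protein and amino acid stress response 12 rose and 1 fell (13 and 3 adjusted over the list alone), including the chaperone cofactor DNAJB9 (2.31), the mTOR inhibitor DDIT4 (2.27) and HERPUD1 (1.07). Camera adjusted p-values were 1.47e-05, 0.000135, 0.000135 and 0.00128, and with an estimated correlation adjusted p = 0.00987, 0.0235, 0.0345 and 0.0431. Against the control siRNA in place of the control precursor the sterol list had a median of 0.09 and adjusted p = 0.126. The stress response list then had 13 genes up and 5 down (0.0115, lost at adjusted p = 0.114 with an estimated correlation).

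Of 25 published miR-101 targets 13 fell and 3 rose (13 and 4 adjusted over the list alone; camera adjusted p = 0.00664, and 0.0396 as adjusted p with an estimated correlation). The microtubule destabilizer STMN1 (-3.46), the endosomal GTPase RAB5A (-1.86), the chromatin remodeller subunit ARID1A (-1.29) and the GTPase RAC1 (-0.96) were among those that fell. A second, lower STMN1 probe gave -0.02. RAC1 was at -0.09 against the control siRNA and not past the threshold (adjusted p 0.307). Of 12 small RNA pathway genes 6 fell and 0 rose, as adjusted over the list alone, including the Dicer partner PRKRA (-1.46), DGCR8 of the Microprocessor (-0.84) and AGO2 (-0.59). Camera adjusted p was 0.0427, with adjusted p = 0.372 with an estimated correlation. That call was lost without control precursor replicate 2 (adjusted p 0.0623) or miR-101 replicate 2 (0.0945) and with median scaling (0.0718). AGO2 against the control siRNA was at -0.08 and not past the threshold (adjusted p 0.630), 4 of the genes fell, and the camera call (0.0489) was lost at adjusted p = 0.34 with an estimated correlation.

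The largest single rises were in the intermediate filament gene SYNC (3.77, SE 0.0485), the protease inhibitor SERPINB2 (3.77, SE 0.0914) and the collagenase MMP1 (3.61, SE 0.138), followed by GABARAPL1, RIMOC1 (3.01), FSTL1 (2.93), the basement membrane collagen chain COL4A5 (2.90), COMMD10 (2.79) and, ahead of LAMP2, ATP6AP1 (2.74), an accessory subunit of the vacuolar proton pump. The largest falls were in JPT1 (-3.83, SE 0.0652), STMN1, the coactivator SUB1 (-3.10), the receptor tyrosine kinase AXL (-3.00, SE 0.0353), SMCO4 (-2.87), MARCKSL1 (-2.84), UNG, the proteasome assembly gene POMP (-2.72), the mitochondrial transcription factor TFB2M (-2.63) and KLF2 (-2.49). Against the control siRNA, SYNC (3.40), GABARAPL1 (3.42), SERPINB2 (3.20), JPT1 (-3.27), SUB1 (-3.21) and AXL (-2.34) had log2 changes near these, while LAMP2 (0.84), RIMOC1 (0.82), ATP6AP1 (0.57), FSTL1 (0.51) and COMMD10 (0.34) had much smaller ones, and MMP1 had 1.78.

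In all 6071 genes changed with miR-101 (44.9% of those tested), 3194 of them higher and 2877 lower, and 826 changed at least 2-fold. Against the control siRNA, 3936 of the 6071 (64.8%) were past the threshold with the same sign and 223 with the opposite sign. Of 132 named results with miR-101 other than EZH2, 14 turned sign against the control siRNA, 10 lost their call and 36 kept it with a size that moved by over 1.5 times. Control arrays lay at the first positions of each chip and treated arrays at the last, so position and treatment cannot be told apart within a chip.

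The remaining lists had no camera call with miR-101. Fry, which does not set a list against the other genes, called all of them except PRC1, HOX, NF-kB and ribosomal proteins. Its adjusted p-values for those were 0.811, 0.432, 0.335 and 0.335. They were 2.9e-06 for PRC2, 6.98e-07 for genes reported as repressed by EZH2 and 6.15e-08 for mesenchymal genes. Housekeeping genes (0.0131) and leukocyte markers (1.11e-05) also had fry calls. Of 11 PRC2 subunits 6 fell, among them RBBP7 (-1.45), PHF19 (-1.40) and AEBP2 (-1.02), and 2 rose, among them JARID2 (1.00); camera adjusted p was 0.165. A second PHF19 probe gave -0.35. Of 16 subunits of Polycomb repressive complex 1 (PRC1), 5 rose and 5 fell. Of 19 other chromatin modifiers 9 fell and 2 rose, with UHRF1, which maintains DNA methylation, at -1.91 and the deacetylase HDAC1 at 1.22. HDAC1 against the control siRNA was at 0.10 and not past the threshold (adjusted p 0.304). Of 19 genes reported as repressed by EZH2, 5 fell and 2 rose (camera adjusted p 0.0727). HOX cluster genes gave 4 up and 5 down of 22, with HOXA5 at 1.12. Without control precursor replicate 1 or 3, or miR-101 replicate 1, 3 HOX genes fell. CDK inhibitors and p53 response genes gave 11 up and 3 down of 22, with CDKN2C (1.22) and CDKN1B (1.05) up and BAX (-0.91) down. A second CDKN2C probe gave 0.09. BAX against the control siRNA was at -0.15 and not past the threshold (adjusted p 0.0948). BCL2-family apoptosis regulators gave 1 up and 7 down of 20. Histone genes gave 4 up and 7 down of 18, with the variants H2AX (-1.72) and H2AZ1 (-1.40) among the latter, and against the control siRNA 11 up and 3 down. NF-kB inflammatory genes gave 6 up and 6 down of 16, AP-1 and immediate early genes 7 and 6 of 20, hypoxia and glycolysis genes 6 and 6 of 22, ribosomal proteins 6 and 4 of 42, TGF-beta and BMP signalling 7 and 2 of 21, and WNT signalling 7 and 3 of 24. Against the control siRNA, NF-kB genes gave 12 up and 0 down, with a median of 0.77 in place of 0.11 (camera adjusted p 1.14e-05, and adjusted p = 0.0268 with an estimated correlation). NF-kB genes differed between the controls by a median of -0.89, so that call cannot be told apart from the control difference. AP-1 genes against the control siRNA gave 10 and 2, ribosomal proteins 17 and 3, BCL2-family genes 4 and 5 and WNT signalling 3 and 6. PRC1 subunits gave 2 and 2, p53 response genes 7 and 1 and hypoxia genes 9 and 4. The histone, ribosomal and chromatin modifier lists had camera calls against that control (0.00449, 0.0276 and 0.0276), lost at adjusted p = 0.221, 0.24 and 0.221 with an estimated correlation. Epithelial genes gave 4 up and 0 down of 9, with the tight junction gene CLDN1 at 1.52, mesenchymal genes 8 and 3 of 23, with ACTA2 at 1.67, urothelial genes 0 and 4 of 11, and housekeeping genes 2 and 5 of 15, with the prolyl isomerase PPIA at -1.96. Among markers of other cell types, 1 of 4 leukocyte genes (CD68, 0.98), 1 of 6 endothelial genes (ENG, 0.63), 3 of 8 neuronal genes and 3 of 5 erythroid genes rose and 0 fell. CD68 and ENG were chosen after their values were seen. Adjusted over the list alone, the counts up and down were 6 and 5 for PRC1, 3 and 9 for chromatin modifiers, 11 and 4 for p53 response, 9 and 3 for mesenchymal genes, 4 and 8 for histones, 4 and 4 for ribosomal proteins, and 2 and 0 for neuronal markers. For the other lists of this paragraph they were as given.

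**Figure D2:**
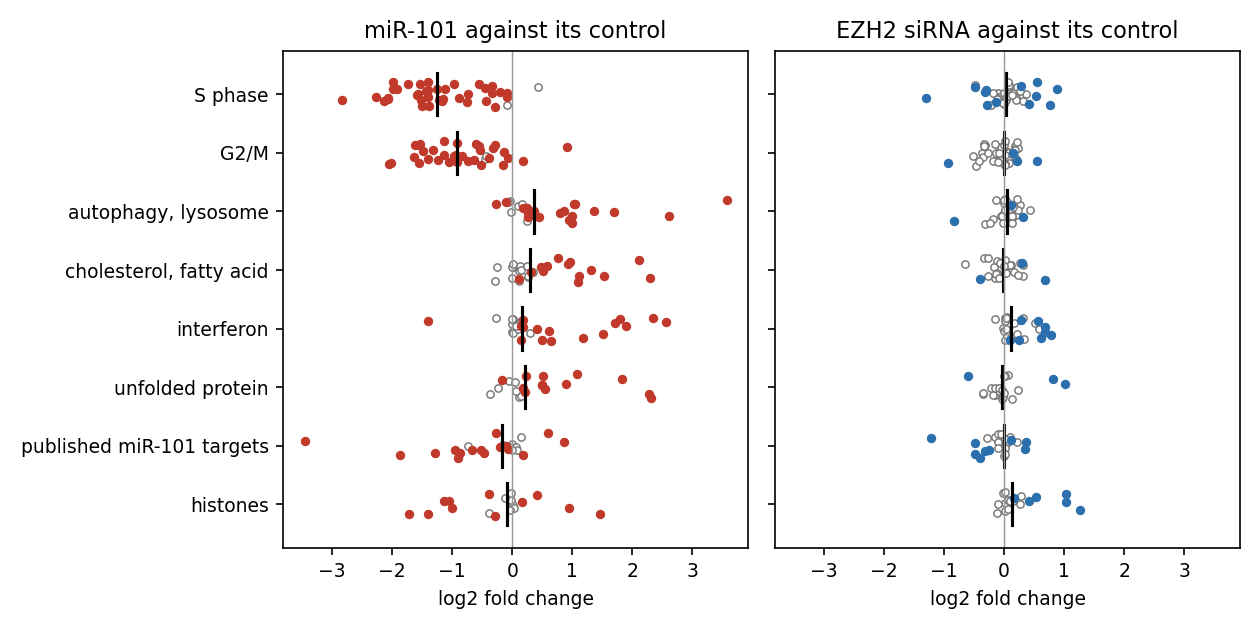
Log2 fold changes of the members of 8 gene lists with miR-101 against control precursor and with EZH2 siRNA against control siRNA, 1 point per gene, filled where the adjusted p was under 0.05, with a black line at the median. With miR-101 the S phase median was -1.25 and the G2/M median -0.93, and with EZH2 siRNA they were 0.03 and 0.00.

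EZH2 siRNA, set against the control siRNA, was followed by higher messenger RNA of interferon response genes. Of 28 interferon response genes 8 rose and 0 fell (11 and 0 adjusted over the list alone), including IFI6 (0.78), IFI35 (0.68) and the immunoproteasome subunit PSMB8 (0.62). Of 18 histone genes 6 rose and 0 fell, as adjusted over the list alone, including H2BC5 (1.26), H1-2 (1.03) and H2BC12 (1.02). Camera gave adjusted p = 2.18e-05 and 0.000531. With an estimated correlation the camera calls were lost, at adjusted p = 0.0718 and 0.289. Fry gave adjusted p = 0.000218 and 0.000455. Against the control precursor 15 interferon genes were up and 1 down (camera adjusted p 6.4e-05, and adjusted p = 0.0306 with an estimated correlation). Without control siRNA replicate 1 or 3, or EZH2 siRNA replicate 1, 3 histone genes rose. Against the control precursor the histone median turned to -0.30, with H2BC5 at -0.48, H2BC12 at -0.82 and H1-2 at -1.77. Of the histone genes 1 was then up and 10 down (camera adjusted p 0.000111, lost at adjusted p = 0.184 with an estimated correlation). Histone genes are near-identical copies whose probes may bind more than 1 of them.

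The largest rises were in the chemokine CCL2 (2.15, SE 0.123), the calcium-binding protein CALB2 (1.62), carbonic anhydrase CA12 (1.60), DEPP1 (1.43), RN7SK (1.42), TRIOBP (1.42), IER3 (1.26), H2BC5, CMTM4 (1.24) and the amino acid transporter SLC7A5 (1.18). The small nuclear RNA RN7SK had an SE of 0.345 and an adjusted p of 0.0303. Without control siRNA replicate 2 or 3, or any of the EZH2 siRNA replicates, RN7SK was no longer past the threshold (adjusted p up to 0.111). A second TRIOBP probe gave 0.05. Large falls were in MMP1 (-2.18, SE 0.138), the immediate early transcription factor EGR1 (-2.17, SE 0.0597), the calponin CNN2 (-2.10), the thioesterase LYPLA1 (-1.75), B4GALT6 (-1.70), the phosphatase PTPN1 (-1.65), DSE (-1.60), the kinase HIPK2 (-1.54) and MICB (-1.54), a stress ligand of natural killer cells. A second CNN2 probe gave -0.49. Against the control precursor CCL2 (2.41), CA12 (2.24), DEPP1 (1.58) and TRIOBP (1.56) remained higher, IER3 (-0.84), CMTM4 (-0.35) and RN7SK (-0.24) had the opposite sign, and CALB2 (0.12), SLC7A5 (0.23), B4GALT6 (-0.12) and MMP1 (-0.35) were not past the threshold. EGR1 (-1.26) and DSE (-0.74) had smaller changes against it.

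In all 1419 genes changed with EZH2 siRNA (10.5%), 791 of them higher and 628 lower, and 65 changed at least 2-fold. The count was 894 without control siRNA replicate 2, 791 without control siRNA replicate 3 and 918 without EZH2 siRNA replicate 1. It was 2689 with array weights and 387 with median scaling, where 30.8% of the calls were higher, against 55.7%. Against the control precursor 715 of the 1419 kept their sign past the threshold and 161 were past it with the opposite sign. Of 86 named results with EZH2 siRNA other than EZH2, 22 turned sign, 11 lost their call and 24 kept it with a size that moved by over 1.5 times.

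The other lists given had no camera call with EZH2 siRNA. Fry called the AP-1 (adjusted p 0.000171), TGF-beta and BMP (0.000722), leukocyte (0.00253), published miR-101 target (0.00464), erythroid (0.00751) and hypoxia lists (0.012). It called none of the rest of these lists. Of 19 genes reported as repressed by EZH2, 3 rose, among them the cell cycle inhibitor CDKN1A (0.50) and KLF2 (0.39), and 3 fell, among them IGFBP3 (-0.46) and the WNT antagonist SFRP1 (-0.42); camera adjusted p was 0.996. CDKN1A and KLF2 were not past the threshold with median scaling, and CDKN1A, KLF2 and SFRP1 had the opposite sign against the control precursor (-0.57, -0.14 and 0.42). Of PRC2 subunits only EZH2 was past the threshold, of 11 tested. PRC1 subunits gave 2 up and 2 down, HOX genes 1 and 0, S phase genes 6 and 6, with E2F2 at 0.88 and MCM3 at -1.30, and G2/M genes 3 and 1. TGF-beta and BMP genes gave 6 up and 1 down, with the inhibitors of differentiation ID1 (0.91) and ID3 (0.82) up and the receptor TGFBR2 (-0.91) down (camera adjusted p 0.0545); against the control precursor ID1 was at -0.38 and ID3 at -0.10. NF-kB genes gave 3 and 5, with CXCL8 at -1.24 and CXCL1 at -0.77, and AP-1 genes 4 and 4. Against the control precursor NF-kB genes gave 1 up and 13 down, AP-1 genes 1 and 12 and sterol genes 14 and 0. Camera adjusted p-values were 4.43e-08, 1.45e-05 and 7.5e-05, each 0.0186 as adjusted p with an estimated correlation. Control siRNA against control precursor gave 0 and 10, 1 and 10 and 13 and 0 for the same lists. Against the control siRNA their medians were -0.11, -0.04 and -0.02, so these calls cannot be told apart from the control difference. G2/M genes against the control precursor gave 17 up and 0 down (0.000241, lost at adjusted p = 0.293 with an estimated correlation), where the controls gave 19 and 1. HOX genes then gave 5 and 0, BCL2-family genes 3 and 7 and ribosomal proteins 2 and 9. Autophagy genes gave 9 and 6 against that control, WNT signalling 7 and 3, stress response genes 6 and 5 and mesenchymal genes 8 and 6. Hypoxia genes gave 6 and 4, p53 response genes 5 and 5, small RNA genes 3 and 4 and TGF-beta genes 2 and 3. The counts that follow are against the control siRNA. Counts up and down were 3 and 6 for published miR-101 targets, 3 and 1 for other chromatin modifiers, 3 and 1 for p53 response, 0 and 1 for epithelial genes, 4 and 3 for mesenchymal genes, 0 and 0 for urothelial genes, 2 and 2 for BCL2-family genes, 2 and 1 for sterol synthesis, 2 and 1 for the unfolded protein response, 3 and 0 for hypoxia, 2 and 1 for ribosomal proteins, 1 and 0 for the small RNA pathway, 2 and 1 for autophagy, 0 and 1 for WNT signalling and 1 and 0 for housekeeping genes. Leukocyte markers gave 0 and 1 (CD68, -0.56), endothelial and neuronal markers 0 and 0, and erythroid markers 1 and 0 (HBE1, 0.46), and CD68 and HBE1 were chosen here after their values were seen. Without control siRNA replicate 1 or 3 or EZH2 siRNA replicate 2, 0 chromatin modifiers rose. Without control siRNA replicate 1 or EZH2 siRNA replicate 1, 3 TGF-beta genes rose, and without control siRNA replicate 2 or 3, 3 S phase genes fell. With control siRNA replicate 1 or 3 or EZH2 siRNA replicate 1 or 2 left out, 1 miR-101 target and 1 G2/M gene rose, and 1 G2/M gene rose without EZH2 siRNA replicate 3. With control siRNA replicate 2 or 3 or EZH2 siRNA replicate 1 or 2 left out, 1 hypoxia gene rose. NF-kB genes that fell numbered 3 without control siRNA replicate 2 or EZH2 siRNA replicate 3 and 2 without EZH2 siRNA replicate 1.

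Adjusted over the list alone, the counts up and down with EZH2 siRNA were 2 and 2 for PRC2, 4 and 1 for chromatin modifiers, 4 and 6 for miR-101 targets, 0 and 0 for HOX genes, 4 and 4 for G2/M, 10 and 7 for S phase, 5 and 2 for p53 response, 3 and 6 for NF-kB, 4 and 5 for AP-1, 2 and 2 for epithelial genes and 5 and 4 for mesenchymal genes. They were 3 and 6 for the BCL2 family, 5 and 2 for sterol synthesis, 2 and 0 for the small RNA pathway, 7 and 1 for TGF-beta, 0 and 1 for endothelial markers and 3 and 0 for erythroid markers, and unmoved for the other lists without a camera call.

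The responses to miR-101 and to EZH2 siRNA shared some genes and opposed in others. Higher with both were DEPP1 (1.80 and 1.43), CCL2 (1.30 and 2.15), TRIOBP (1.27 and 1.42), IER3 (1.68 and 1.26), H2BC5 (1.46 and 1.26), the retinol enzyme DHRS3 (1.17 and 1.17), CA12 (1.02 and 1.60) and DDIT4 (2.27 and 1.02). Lower with both were LYPLA1 (-1.55 and -1.75), the secreted hormone STC1 (-1.72 and -1.36), the helicase subunit MCM3 (-2.07 and -1.30), VSTM1 (-1.77 and -1.11), cyclin D1 (CCND1, -1.26 and -1.09), the polyadenylation factor NUDT21 (-1.22 and -1.05), MARCHF4 (-1.46 and -1.02) and NETO2 (-2.46 and -0.99). A second TRIOBP probe gave -0.07 with miR-101 and 0.05 with EZH2 siRNA. In the EZH2 siRNA comparison against the control precursor, IER3 (-0.84), H2BC5 (-0.48) and STC1 (0.31) had the opposite sign, NUDT21 was at -0.49, and DDIT4 (1.90) and VSTM1 (-2.09) had larger changes. In the miR-101 comparison against the control siRNA, CA12 (0.38), VSTM1 (-0.79), MARCHF4 (-0.97) and DDIT4 (1.38) had smaller changes and IER3 (3.78), H2BC5 (3.20) and STC1 (-3.39) larger ones. In all 963 genes changed with both treatments, 538 the same way and 425 in opposite ways. Of the 538, 329 were higher, against 187 for independent lists, and 209 were lower, against 134. Opposite pairs numbered 200 and 225, against 148 and 168, so pairs of either kind exceeded independent lists. Both comparisons share 1 estimate of the spread per gene, so their lists are not independent. An excess over independent lists therefore does not show a shared response. Among the 963, which are not independent of one another, the odds ratio of the directions was 1.53. Of the 826 genes changed at least 2-fold with miR-101, 54.4% had the same sign with EZH2 siRNA, and with the controls exchanged 43.5% of 740 genes that differed at least 2-fold had it. With the controls exchanged 986 genes changed the same way. The exchange takes the control difference from the miR-101 change and adds it to the EZH2 siRNA change, so both exchanged values mix it in. Across all genes, which are not independent replicates, Pearson's r of the fold changes was 0.0455 and Spearman's rank correlation 0.0508. The count of 538 was 334 without control siRNA replicate 2, 298 without control siRNA replicate 3, 336 without EZH2 siRNA replicate 1, 124 with median scaling and 1117 with array weights.

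**Figure D3:**
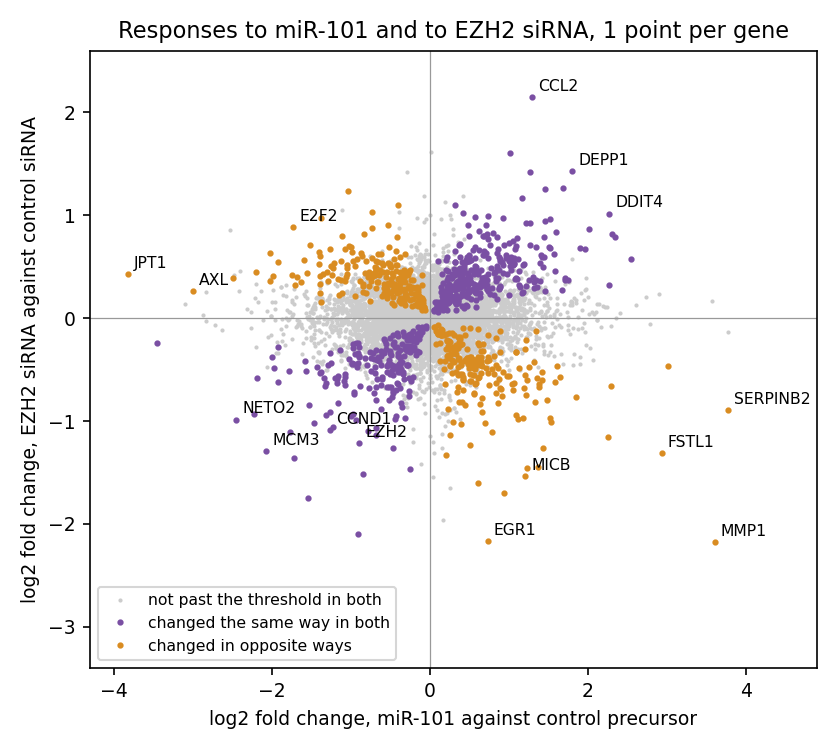
Log2 fold change with EZH2 siRNA against that with miR-101, each against its own control, 1 point per gene, with purple for the 538 genes changed the same way, orange for the 425 changed in opposite ways and grey for the rest. The labelled MMP1 lies at 3.61 and -2.18, and CCL2 at 1.30 and 2.15.

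A direct test of the difference between the responses found 4579 genes, 2354 with a higher value for miR-101 and 2225 with a lower one. The largest differences were in MMP1 (5.79), SERPINB2 (4.67), FSTL1 (4.24), SYNC (3.91) and RIMOC1 (3.48) on one side and JPT1 (-4.26), AXL (-3.27), SUB1 (-3.23), STMN1 (-3.21) and MARCKSL1 (-3.09) on the other. With the controls exchanged, a comparison that crosses chips, RIMOC1 turned to -0.91, FSTL1 was at -0.60 (adjusted p 0.0506), and MMP1 (2.14), AXL (-1.95) and MARCKSL1 (-1.82) had smaller differences, while SERPINB2 (3.53), SYNC (3.17), JPT1 (-3.15), SUB1 (-3.46) and STMN1 (-3.59) stayed nearer. Of the 4579 genes 2012 (43.9%) differed then with the same sign and 768 with the opposite sign, in all 5503. Among the lists, S phase genes differed in 34 of 39 members, all lower with miR-101 (camera adjusted p 2.14e-18, and adjusted p = 0.00244 with an estimated correlation). G2/M genes were lower in 28 and higher in 1 of 36 (9.30e-11, and adjusted p = 0.0437 with an estimated correlation). Autophagy genes were higher in 16 and lower in 2, sterol genes higher in 13 and lower in 0, and unfolded protein response genes higher in 10 and lower in 1, all with calls under both correlations when each treatment was set against its own control. The histone list (2 higher, 11 lower) and the small RNA list (0 higher, 4 lower) had camera calls at 0.00282 and 0.0196 that were lost at adjusted p = 0.256 and 0.421 with an estimated correlation. Adjusted over the list alone, the counts were 34 for S phase, 29 and 1 for G2/M, 17 and 2 for autophagy, 11 and 1 for the unfolded protein response, and as given for the others. With the controls exchanged the S phase and G2/M calls held (adjusted p = 0.00763 and 0.0142 with an estimated correlation). The exchange moved the G2/M median from -0.85 to -1.53 and the S phase median from -1.23 to -1.31. Sterol genes then gave 4 higher and 8 lower (camera adjusted p 0.594), stress response genes 12 and 6 (0.0716) and small RNA genes 1 and 3 (0.22). Autophagy genes gave 14 and 3 (0.0169, lost at adjusted p = 0.0784 with an estimated correlation). Histone genes turned to 12 higher and 3 lower (0.000229, lost at adjusted p = 0.154 with an estimated correlation), and NF-kB genes gave 14 and 1 and AP-1 genes 10 and 1 (2.34e-08 and 0.00022, and adjusted p = 0.0142 for each with an estimated correlation). Published miR-101 targets gave 4 and 11, chromatin modifiers 1 and 9 and ribosomal proteins 16 and 3, with camera calls at 0.031, 0.0136 and 0.0121 that were lost at adjusted p = 0.101, 0.211 and 0.223 with an estimated correlation. The exchange takes 2 times the difference between the controls from each gene's difference. Median control differences were -0.89 for NF-kB, -0.465 for histone, 0.34 for G2/M, -0.19 for AP-1 and -0.0015 for S phase genes. The exchanged calls of the NF-kB, histone and AP-1 lists cannot be told apart from the difference between the controls. The exchanged G2/M call mixes that difference in, so it adds no support to the call against each treatment's own control. The interferon list had no camera call for the difference (adjusted p 0.0612), while fry gave adjusted p = 7.58e-05. It had a camera call in both treatments, of which that with EZH2 siRNA was lost at adjusted p = 0.0718 with an estimated correlation. With median scaling 2713 genes differed.

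The control transfections differed from each other in 3823 genes, 1901 higher and 1922 lower in the control siRNA arrays. Of 16 NF-kB inflammatory genes 10 were lower and 0 higher with the control siRNA (12 and 0 adjusted over the list alone), including the inhibitor NFKBIA (-2.38). Of 28 sterol and fatty acid genes 13 were higher and 0 lower, as adjusted over the list alone. AP-1 genes gave 1 higher and 10 lower of 20, as adjusted over the list alone. Camera adjusted p-values were 1.61e-07, 1.56e-05 and 0.00151, and adjusted p = 0.0233, 0.0233 and 0.0407 with an estimated correlation. Histone genes gave 1 higher and 11 lower, G2/M genes 19 higher and 1 lower, and ribosomal proteins 2 higher and 13 lower (1 and 12, 22 and 3, and 2 and 13 adjusted over the list alone). Those calls were lost at adjusted p = 0.0875, 0.215 and 0.323 with an estimated correlation. The largest differences were in PKIA (3.04), GNA13 (2.49), TXNDC5 (2.45), COMMD10 (2.44) and GFPT2 (2.42), higher with the control siRNA, and COXFA4L3 (-3.35), H1-2 (-2.81), NFKBIA, SNORD46 (-2.26) and H2BC12L (-2.21), lower with it. The controls were on different chips, so chip and transfection cannot be told apart in this comparison. With median scaling 2215 genes differed and 75.6% were higher, against 49.7%.

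**Figure D4:**
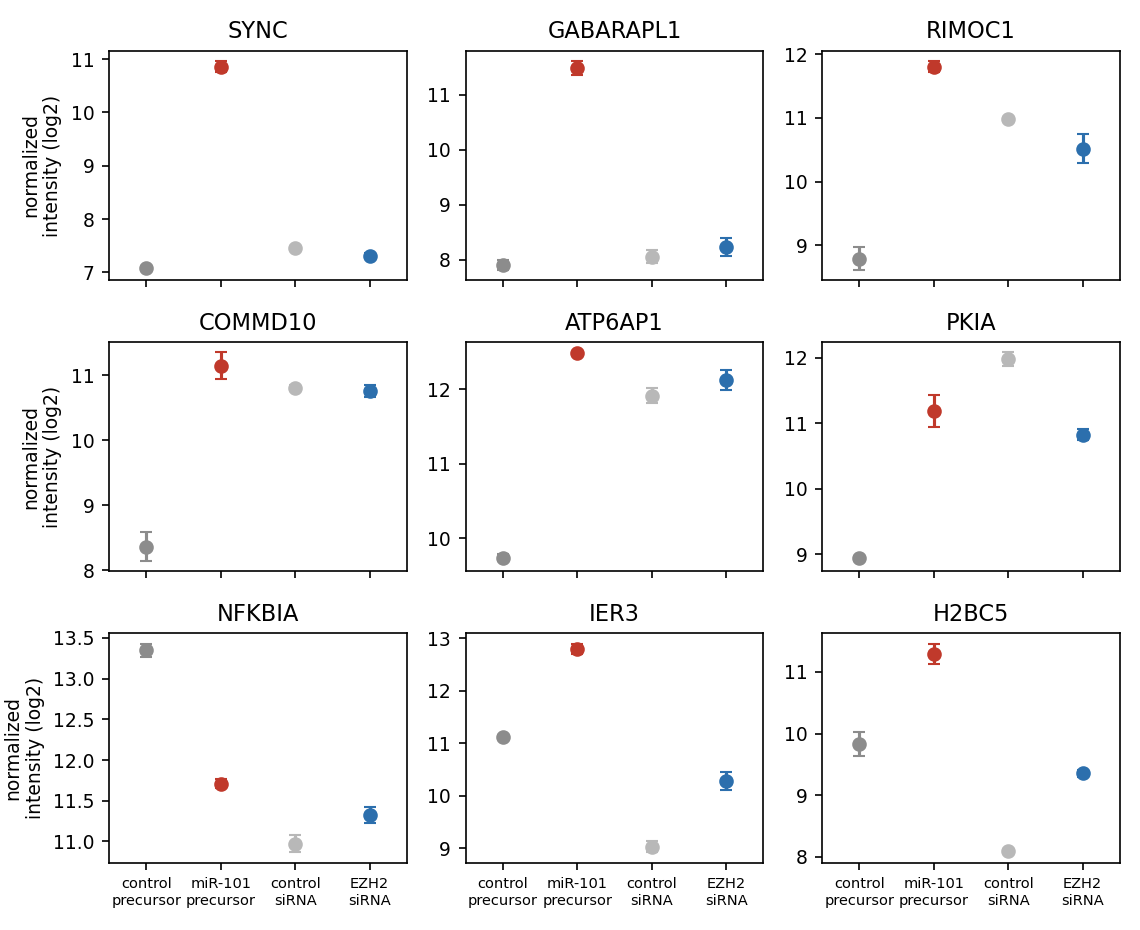
Normalized log2 intensity of 9 genes in the 4 groups, as group mean ± SD (n = 3). COMMD10, RIMOC1, ATP6AP1 and PKIA were higher in every other group than in the control precursor group, whereas SYNC and GABARAPL1 rose with miR-101.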

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

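The tests with the controls exchanged, of a chip difference, of noise in the shared control arrays and of a position step alike on both chips were chosen after the results were seen, and those of array brightness and of a gradient along the chip before.

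Directions opposed in 425 genes past the threshold with both treatments, which places the difference of each past its threshold by construction. The differences in log2 response, miR-101 minus EZH2 siRNA, were 5.79 for MMP1, 4.67 for SERPINB2, 4.24 for FSTL1, 3.48 for RIMOC1, -4.26 for JPT1 and -3.27 for AXL. With the controls exchanged, which crosses chips, they were 2.14, 3.53, -0.60, -0.91, -3.15 and -1.95, so that FSTL1 and RIMOC1 turned sign. Probes without a gene name, which entered no comparison of genes, also changed: 362 of 3127 (11.6%) with miR-101, 174 higher and 188 lower, and 55 (1.76%) with EZH2 siRNA, 21 higher and 34 lower.

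The control precursor arrays stood apart from the other groups. Of genes that differed between the controls, 1999 changed with miR-101 in the direction of the control siRNA (1025 higher and 974 lower, against 449 and 409 for independent lists), and 254 and 253 changed against it. Both comparisons share the control precursor arrays, so noise alone would also give more genes than independent lists. A difference between chips would place the control precursor and miR-101 arrays together, but over genes chosen without it each held-out control precursor array lay away from the miR-101 arrays, by a median of at least 0.182 log2, which argues against the chip as the whole cause. Noise in the shared control arrays gave a covariance of 0.00403 on average and at most 0.00443 in 100 simulations, against 0.0655 observed, a difference of 0.0615 (correlation 0.402, simulated 0.498). The simulated noise was independent between arrays, so it could not show a shift common to the control precursor arrays. A response of the cells to the control precursor itself, another shift common to its arrays and a chip part of the difference stay open.

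The fall of S phase and G2/M genes with miR-101 was set against the dimmer arrays of that group, whose mean brightness (95th percentile of signal) lay -0.299 log2 from the control. Replicate 1 was not dimmer, at 1520 against 1289 to 1428 on the control precursor arrays. Over 75 genes the median change was -1.05, and it was -1.08, -0.94 and -1.07 on the 3 miR-101 arrays. The slope on brightness within groups gave -0.662% of the fall (95% interval -4.01% to 2.68%), which argues against brightness as its cause. On the siRNA chip, which had the same layout, the medians of the lists were 0.03 and 0.00, and the 3 EZH2 siRNA arrays showed -1.92% to -0.284% of the fall, which argues against a position step alike on both chips. A biological effect of miR-101 stays a hypothesis, and a position step on the miR-101 chip alone stays open.

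Genes changed the same way by both treatments could reflect position, since treated arrays lay last on both chips. Over 155 genes a linear gradient predicted 0.566 log2 between the last and first position of each group. The observed shares of that were 21.1%, 8.02%, -9.50% and 2.41%, all under the bound of 25%, which argues against a linear gradient. A step between the first and last 3 positions cannot be told apart from treatment.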

How the results depend on the processing

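The tests against the other control, with the controls exchanged, with each chip normalized on its own and with an intensity trend were chosen after seeing the data. EZH2 fell past the threshold under every alternative run, from -1.06 to -0.74 with miR-101 and from -1.34 to -1.14 with EZH2 siRNA. Median scaling gave 387 genes for EZH2 siRNA, 2713 for the difference, 2215 between the controls and 124 changed alike, and calls were higher in 30.8% with EZH2 siRNA and 75.6% between the controls. Array weights gave 2689 for EZH2 siRNA and 1117 changed alike. At 1.5-fold or more the counts were 2241 for miR-101, 333 for EZH2 siRNA, 2357 for the difference and 1057 between the controls, by construction of the threshold. Against the control precursor EZH2 siRNA gave 3865 genes, and with the controls exchanged 986 changed alike and the difference turned for FSTL1 (-0.60) and RIMOC1 (-0.91). Leaving out 1 array gave 5297 to 5706 genes for miR-101, 791 to 1139 for EZH2 siRNA, 3979 to 4580 for the difference, 2839 to 3247 between the controls and 298 to 599 changed alike, with fewer arrays in each fit. EZH2 then ranged from -1.05 to -0.80 with miR-101 and from -1.27 to -1.15 with EZH2 siRNA. EZH2 siRNA counts moved most without control siRNA replicate 2 (894, and 334 alike), control siRNA replicate 3 (791 and 298) or EZH2 siRNA replicate 1 (918 and 336). With the replicate number as a block the counts were 6044, 1436, 4615, 3917 and 539. Deviations of arrays with the same number correlated at -0.125 to 0.369, and only 2 of 6 matched their own number best. This gave no sign that the numbers pair the arrays, but so few arrays cannot exclude it. A chip block leaves comparisons within a chip as they are, and as a random block it was not run, since each group lies on 1 chip. Of 238 named results, 45 lost their call and 0 reversed in an alternative chosen beforehand; median scaling ended 41 calls, 34 of them with EZH2 siRNA. The cause of these changes was not tested.

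Against the control siRNA, with miR-101, the sign turned for CBX6 (0.97), CDKN1A (0.37), NFKBIA (0.74), TNFAIP3 (0.61), EGR1 (-0.18), TJP1 (-1.01), TGFBI (1.13), IRF1 (0.31), UPK1B (0.00017), BID (0.38), DKK3 (-0.26), CTNNB1 (-0.63), FZD1 (-0.0028) and TUBB3 (-1.07). With EZH2 siRNA against the control precursor it turned for RN7SK (-0.24), IER3 (-0.84), H2BC5 (-0.48), CMTM4 (-0.35), RYBP (-0.31), CBX6 (-0.99), SFRP1 (0.42), CDKN1A (-0.57), KLF2 (-0.14), CDC25B (-0.0507), E2F1 (-0.31), TGFBI (-0.82), BCL2 (0.13), FADS1 (0.0049), SLC2A1 (-0.30), H2BC12 (-0.82), H1-2 (-1.77), H4C14 (-0.42), NEU1 (-0.55), ID1 (-0.38), ID3 (-0.10), STC1 (0.31) and the histone list (median -0.30). These comparisons cross chips, so chip and transfection cannot be told apart in them. Signal over background limits the rest: about 33.1% to 35.1% of probes were detected, and fold changes near the background are understated.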

Other observations

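The test of EZH2 as the whole cause of the miR-101 response and the count of splits that kept the miR-101 comparison were chosen after the results were seen, and the tests over other splits of the arrays before.

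The largest axis of variation over the 12 arrays carried 52.8% of the variance and set the 3 miR-101 arrays (37.2 to 39.2) apart from the other 9. The next carried 25.1% and placed the control precursor arrays at -22.8 to -27.5, with the miR-101 arrays near 0 and both siRNA groups above it. The axis after that (9.88%) parted EZH2 siRNA from control siRNA. Of the 826 genes changed at least 2-fold with miR-101, 711 (86.1%) kept their sign past the threshold against either control, among them SYNC, GABARAPL1, SERPINB2, JPT1, SUB1 and AXL. The comparisons with either control share the treated arrays, so a shift in those arrays would also be kept. CCL2, the monocyte chemoattractant, rose with both treatments against either control, by 1.30 and 1.03 with miR-101 and by 2.15 and 2.41 with EZH2 siRNA. DEPP1 did so as well, by 1.80 and 1.65 and by 1.43 and 1.58.

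A hypothesis, that lower EZH2 messenger RNA is the whole cause of the miR-101 response, would have most genes move the same way in both. Of the 826 genes changed at least 2-fold with miR-101, 54.4% moved the same way with EZH2 siRNA (52.5% to 56.7% without single arrays). That was under a bound of 60%, which was also set after the results were seen. Among them 113 were past the threshold the same way and 87 the opposite way, and the median size of change was 0.196 log2 with EZH2 siRNA, against 1.30 with miR-101. With the controls exchanged, 740 genes differed at least 2-fold and 43.5% had the same sign. The exchange takes the control difference from the miR-101 change and adds it to the EZH2 siRNA change. That share therefore mixes in the control difference and adds no support. The shares and sizes against each treatment's own control argue against lower EZH2 messenger RNA as the whole cause, although protein was not measured. A part of the response through EZH2 stays open.

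For miR-101 against its control, 1 of the 10 splits of the 6 arrays gave as many genes as the real 6071, and the highest other gave 6. For EZH2 siRNA it was 1 of 10 (1419, highest other 1), and for the controls 1 of 10 (3823, highest other 0). These splits are too few for a share under 0.05. For the difference of responses 2 of 100 splits within chips gave as many genes (4579 real, highest other 4911). Splits that mixed miR-101 with control precursor arrays gave at most 277 genes, because regrouped arrays call few genes. The share therefore does not test whether chance gave the difference. With the miR-101 comparison kept and the siRNA arrays regrouped, 7 splits gave 3383 to 3903 genes, so a count near that size does not need a response to EZH2 siRNA. For genes changed alike it was 1 of 100 (538 real, highest other 425), but 98 of the splits gave 0 because regrouped arrays call few genes, so this does not test whether the overlap of the responses exceeds chance. Both highest others came from the real split with the sign of 1 comparison turned.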
